A study of Mus musculus with 4 samples.

How the data were processed

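RNA was sequenced from microglia, the resident macrophages of the brain, sorted by fluorescence from mouse telencephalon at embryonic day 14. Per the labels' protocols, total RNA from the sorted cells was made into libraries with a kit that does not mark strand. The labels list 4 samples, 2 from conditional Arid1a knockouts (Arid1a cKO, replicates 1 and 2) and 2 from floxed controls (control, replicates 5 and 6). The tables used here hold values for 3 libraries, knockout replicate 2 and both controls. Knockout replicate 1 was not analysed here. The labels do not say whether each sample came from 1 embryo or a pool, nor that the samples came from separate animals, so p-values measure only the spread between these samples, which may be technical.

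Per the submitters' processing notes, Bowtie2 2.2.3, TopHat2 2.0.12 and HTSeq 0.6.0 were used, and the genome build named is mm9. The gene positions deposited in the tables are not those of that build. Of the gene IDs found in GENCODE M21, 89.9% had a position identical to that annotation on GRCm38 and 99.9% overlapped it, so coordinates are given as the files give them, on GRCm38. The authors deposited 2 tables, each setting knockout replicate 2 beside 1 control. Each holds raw read counts per gene for the 2 libraries, and a normalised column, which the deposited values show to be CPM, the count scaled by the library total, with a count of 0 replaced by 0.5 reads. Each also holds the authors' fold change as a ratio, its log2 value, a p-value and an adjusted p-value. The test behind these p-values was not given in the sources used here. The deposited adjusted p-values were a median of 0.153 and 0.192 times those that Benjamini-Hochberg adjustment of the deposited p-values gives, so the authors' adjusted values are not used to call genes. The genes that the authors marked as significant were those with a p-value under 0.01 and a change of over 3-fold.

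The deposited counts summed to a total of 17262261 reads in the knockout library, 18608979 in control 5 and 13774075 in control 6. The totals implied by the authors' CPM exceeded these sums by 2181, 756 and 2068 reads. A single read was worth 0.0579, 0.0537 and 0.0726 CPM. The tables share 16655 genes, and the knockout counts of all of these were identical in the 2 tables. A further 574 genes stood only in the table with control 5 and 1297 only in the table with control 6, with at most 4 knockout reads each. A gene listed in 1 table has no count for the other control, and was tested only where stated, with the missing count set to 0. The shared set thus leaves out genes with few knockout reads. Among the shared genes, 175 had 0 reads in the knockout library, 2696 in control 5 and 1219 in control 6, so the libraries did not enter alike. In the files 21 gene symbols had been turned into dates, and all 21 were restored from the gene ID.

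Counts of the 16655 shared genes were analysed with edgeR 4.0.16 in R 4.3.3. After edgeR's filterByExpr, 15236 genes were tested with TMM factors of 1.059, 0.963 and 0.981, a quasi-likelihood F test in the version's default form and Benjamini-Hochberg adjustment, two-sided, with a threshold of 0.05. With 1 knockout and 2 control libraries, 1 residual degree of freedom comes from the controls alone, and the knockout library is assumed to vary like them. The common dispersion was 0.438. CPM values printed below are TMM-scaled. Standard errors (SE) of log2 fold changes come from the fold change and its F statistic. Library log2 ratios used a prior count of 2. For a gene with 0 reads in a group, the fold is a bound computed at 3 reads per library. Intervals are exact Poisson intervals at the 95% level, and intervals and floors cover counting error only, since PCR duplicates are not independent molecules.

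Before the data were examined, 32 gene lists, the rule for naming genes and the alternatives given first below were fixed. The 30 lists with at least 5 tested members were tested with camera in limma 3.58.1 on voom values, with a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. With an estimated correlation the test rests on the 1 residual degree of freedom, so it had little power to call any list. The rule named Arid1a and Prg3 whatever their values. Prg3 was put there from recall of a published study of this mouse, so its choice is not independent of earlier findings. It then named up to 12 genes per direction that passed the test, had a mean of 5 CPM or more and differed at least 2-fold from both controls, largest fold change first, leaving out predicted genes, non-coding small RNAs, pseudogenes and sex-linked genes. Where fewer than 5 genes of a direction passed, the list was filled without the test. For each gene list it named up to 4 members with the smallest p at a mean of 5 CPM or more, or the 3 most abundant where the list did not move.

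Alternatives were DESeq2 1.42.0 size factors, upper-quartile factors, other low-count filters, the DESeq2 Wald test, edgeR's likelihood ratio test, limma-voom, other thresholds and each control left out. Alternatives chosen after seeing the data were genes in either table, edgeR's bias-adjusted quasi-likelihood, protein-coding genes only, list members at a mean of 5 CPM or more and, for the share of genes on the same side of both controls, each control as the odd library. The quasi-likelihood was first run in the bias-adjusted form, and the version's default then replaced it because the planned test names no other form. Both had been seen by then.

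The tests were tested on simulated data, with counts drawn for the 15236 genes in 5 runs. In these runs only genes at a mean of 5 CPM or more were changed, so recovery of less abundant genes was not measured. The edgeR quasi-likelihood test recovered 0.8% of genes changed 2-fold, 44.4% of those changed 4-fold, 77.2% at 8-fold and 89.6% at 16-fold, and 5% of its calls were false. Each gene was drawn at the dispersion fitted for its abundance, with no spread of its own. These rates may therefore not hold in the data. The list test called the hypoxia and glycolysis list, shifted by 1 on the log2 scale, in 20 of 20 runs. It called none of 577 tests of other lists in those runs. Genes were drawn independently of each other, so these runs cannot show false calls in lists whose genes move together. The homeostatic list, for example, had an estimated correlation of 0.441 in the data. To ask what a knockout library with no change would give, 100 unchanged libraries were drawn against the real controls from a negative binomial at the fitted dispersion, centred on the mean of the 2 controls. Exon overlaps were read from GENCODE M21. Figures were drawn with matplotlib 3.10.9.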

Results

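Transcript levels were measured by RNA sequencing in microglia from embryonic day 14 mice with a conditional deletion of Arid1a, a DNA-binding subunit of the BAF chromatin remodelling complex, and in microglia from floxed controls. The study's title places the work in the control of microglia homeostasis and the response of neural progenitors. Values were analysed for 1 knockout library (Arid1a cKO replicate 2, 17262261 counted reads) and 2 control libraries (control 5 with 18608979, control 6 with 13774075). Knockout values therefore have no replicate error, and control values are given as mean ± SD with n = 2.

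The targeted gene was read in all 3 libraries. Arid1a (ENSMUSG00000007880, chromosome 4, 133679008 to 133756769, minus strand) had 1258 reads in the knockout library, 1952 in control 5 and 1760 in control 6. This gave 68.9 CPM in the knockout library (exact Poisson interval 65.1 to 72.8) against 120 ± 15.1 CPM in controls (SD, n = 2). The knockout was the lowest library, in the direction of its label, with a log2 fold change of -0.80 (SE 0.41) that did not pass the test (adjusted p = 0.901). The counts cover the whole gene, and a floxed allele loses only part of it, so reads from the remaining exons can persist.

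Plppr4 and Gdf3 rose in the knockout library, and Atp8a2, Rtn4rl1, Siglech and Gm10134 fell. Plppr4, a phospholipid phosphatase-related membrane protein, stood at 216 CPM against 6.52 ± 2.94 CPM in controls (SD, n = 2), a log2 fold change of 5.04 (SE 0.50). Gdf3, a ligand of the TGF-beta superfamily, stood at 252 against 13.5 ± 3.95 CPM, a log2 fold change of 4.22 (SE 0.43). Siglech, a sialic acid-binding lectin widely used as a microglia marker, fell to 58.3 CPM from 988 ± 98.1 CPM (log2 fold change -4.08, SE 0.42). Rtn4rl1, a Nogo receptor family member, stood at 1.59 against 77.4 ± 0.827 CPM, and the phospholipid flippase gene Atp8a2 had 0 reads in the knockout library against 677 and 697 in the controls, at least 272-fold lower.

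These 6 genes passed among 15236 tested, 2 higher and 4 lower (adjusted p from 0.0324 to 0.0374, edgeR quasi-likelihood). Gm10134, a predicted gene outside the naming rule and named after its values were seen, had 1.48 CPM against 114 ± 15.0 CPM. At an unadjusted p under 0.05 there were 914 genes, 375 higher and 539 lower, where 762 would be reached by chance. With control 5 as the odd library 1971 genes reached that unadjusted p, and with control 6 it was 117. With DESeq2 size factors, upper-quartile factors or no low-count filter, edgeR called 0 genes (895, 818 and 948 at that unadjusted p), and the adjusted p of these 6 reached 0.182. The DESeq2 Wald test called 222, 67 higher and 155 lower, and the edgeR test called 44 among genes at 5 CPM or more in 2 libraries.

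**Figure D1:**
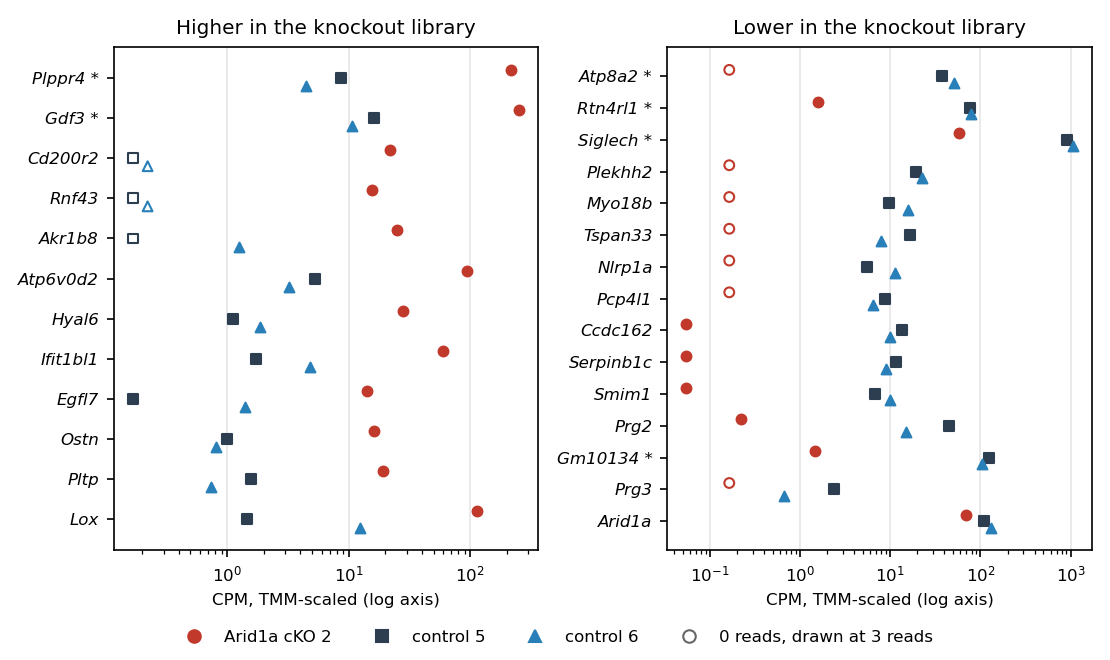
CPM (TMM-scaled, log axis) of the genes named by rule, with Prg3, Arid1a and Gm10134, in the knockout library (circles), control 5 (squares) and control 6 (triangles). Open symbols mark 0 reads and are drawn at 3 reads, asterisks mark genes past the test, and Arid1a at 68.9 CPM in the knockout lies near its controls while Siglech at 58.3 CPM lies far from its own.

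Of the other genes higher in the knockout library than in both controls, none passed the test. The largest differences by rule, from 315 that met the size criteria, included Cd200r2, a CD200 receptor family member, with 398 reads against 0 in each control (at least 112-fold higher, adjusted p = 0.0773). Rnf43, a ubiquitin ligase that restrains Wnt receptors, had 282 reads against 0 in each control (at least 79.2-fold higher, adjusted p = 0.118). Atp6v0d2, a subunit of the vacuolar proton pump, had 93.9 CPM against 5.25 in control 5 and 3.26 in control 6 (adjusted p = 0.056). Ifit1bl1 had 59.7 CPM against 3.27 ± 2.18 CPM, and Hyal6 had 28.1 against 1.12 in control 5 and 1.85 in control 6. Lox, the collagen cross-linking lysyl oxidase, had 113 CPM against 1.45 in control 5 and 12.4 in control 6. Akr1b8 (25.1 CPM against 0.630 ± 0.891), Pltp (19.3 against 1.15 ± 0.582), Ostn (293 reads against 18 and 11) and Egfl7 (14.2 against 0.788 ± 0.877) completed the set. In 4 of the genes named for the largest changes, a gene on the opposite strand covers 10% or more of exon bases (Atp8a2 14.1%, Ostn 12.9%, Pltp 19.3%, Smim1 18.1%), and unstranded counts cannot tell its reads apart. The same holds for the list members Csf1r (15.1%), Mpo (15.0%), Cdc25c (12.7%) and Gpi1 (11.5%), given below.

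Among genes lower in the knockout library, 410 met the size criteria. Plekhh2 had 0 reads against 346 and 307, at least 128-fold lower (adjusted p = 0.0722). Myo18b, an unconventional myosin, had 0 reads against 174 and 210 (at least 77.0-fold lower), and Tspan33 had 0 against 295 and 106 (at least 74.1-fold lower). Nlrp1a, an inflammasome sensor, had 0 reads against 99 and 152, and Pcp4l1 had 0 against 157 and 86. Ccdc162, Serpinb1c and Smim1 each had 1 read in the knockout library against at least 120 in either control. Prg2, the eosinophil granule major basic protein, had 4 reads against 794 and 203 (adjusted p = 0.118). Its neighbour and paralog Prg3 (ENSMUSG00000027072, chromosome 2, 84988215 to 84993886, plus strand), named from recall of an earlier published study of this mouse, had 0 reads against 43 in control 5 and 9 in control 6. That is at least 9.34-fold lower than the control mean and did not pass the test (adjusted p = 0.899). Most of that difference comes from control 5, with log2 ratios of -4.38 over control 5 and -2.70 over control 6.

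Homeostatic microglia genes fell as a list in the knockout library. Of 37 members, the knockout was the lowest library in 23 and the highest in 9, with a median log2 fold change of -0.50 (camera adjusted p = 1.88e-07; adjusted p = 0.773 with an estimated correlation). Siglech passed over all genes, and 6 members passed when adjusted over the list alone, 5 lower and 1 higher. Beside Siglech, these included Adgrg1 at 5.97 CPM against 123 ± 63.3 CPM in controls (SD, n = 2), Crybb1 at 1.97 against 31.1 ± 1.08 CPM and the microglia surface protein Tmem119 at 583 against 1901 ± 517 CPM. P2ry12, the purinergic receptor that steers microglial processes, had 4073 against 7843 ± 892 CPM. The growth factor receptor Csf1r lay between the controls, at 4101 CPM against 3237 and 6134. The median was -0.15 over control 5 and -0.58 over control 6, and with control 6 as the odd library the list was called higher (adjusted p = 1.74e-09).

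Interferon response genes rose as a list. The knockout was the highest library in 22 of 29 members, with a median log2 fold change of 1.73, or 1.27 over the 23 members at a mean of 5 CPM or more (camera adjusted p = 2.25e-09; adjusted p = 0.773 with an estimated correlation). No member passed over all genes, and 4 passed adjusted over the list alone, all higher. Ifit3 had 74.0 CPM against 17.4 ± 1.19 CPM in controls (SD, n = 2), Rsad2 had 48.0 against 7.68 ± 2.80, Ifit1 had 42.1 against 7.31 ± 0.171 and Oasl2 had 38.9 against 5.04 ± 2.83. With control 6 or control 5 as the odd library the list was called lower (adjusted p = 0.01 and 0.0435). The Ifit genes are close paralogs, among which the counting could divide reads.

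Chemokines and their receptors fell as a list, with a median log2 fold change of -1.38 and the knockout lowest in 12 of 21 members (camera adjusted p = 4.66e-06; adjusted p = 0.773 with an estimated correlation). None passed over all genes, and 9 passed adjusted over the list alone, 8 lower and 1 higher. Ccl9 had 80.6 CPM against 321 ± 23.6 CPM in controls (SD, n = 2) and Ccl6 had 171 against 537 ± 36.5. The monocyte attractants Ccl2 and Ccl7 had 340 against 1693 in control 5 and 906 in control 6, and 54.4 against 380 and 169. The Ccl genes are paralogs, so divided reads cannot be ruled out.

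Genes of activated or axon-tract microglia and of border-associated macrophages rose as lists, by less. In the activated list the median log2 fold change was 0.27 (0.39 over control 5 and 0.56 over control 6) and the knockout was highest in 17 of 27 members (camera adjusted p = 0.00741; adjusted p = 0.773 with an estimated correlation). No member passed over all genes, and 10 passed adjusted over the list alone, 7 higher and 3 lower. Gpnmb, a lysosomal glycoprotein, had 983 CPM against 219 ± 21.8 CPM in controls (SD, n = 2), Hpse had 121 against 30.0 ± 1.03 and the lectin Clec7a had 94.5 against 15.8 ± 7.78. Axl, a receptor tyrosine kinase for dying cells, went the other way, with 18.9 against 114 ± 10.7 CPM. In the border macrophage list the median was 0.41 (0.37 over control 5, 0.74 over control 6, and 0.08 over the 11 members at a mean of 5 CPM or more), with the knockout highest in 10 of 19 members (camera adjusted p = 0.0205; adjusted p = 0.773 with an estimated correlation), and 3 members passed adjusted over the list alone and none over all genes. These were Ednrb (348 CPM against 74.8 ± 11.5), Dab2 (1131 against 348 ± 3.29) and Ms4a6b (686 against 195 ± 68.5), while Mrc1, a mannose receptor typical of those cells, had 243 against 229 ± 18.2 CPM. With no low-count filter the adjusted p was 0.146 for the activated and 0.155 for the border list.

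**Figure D2:**
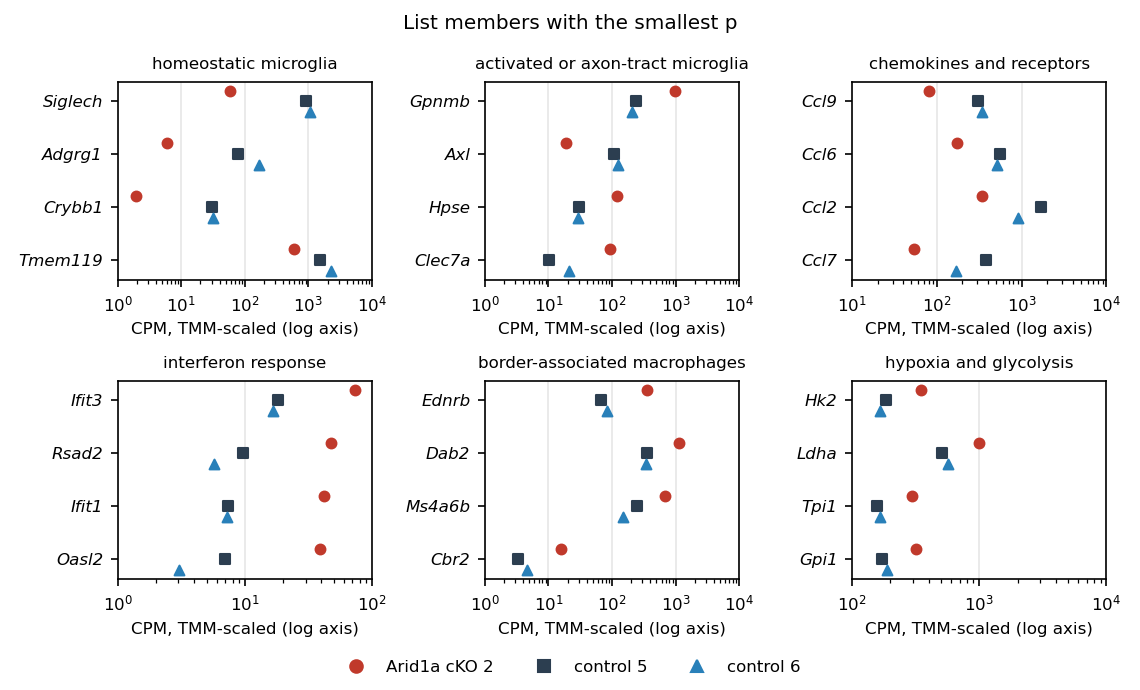
CPM (TMM-scaled, log axes that differ between panels) of the 4 members with the smallest p in each of 6 gene lists, in the knockout library (circles), control 5 (squares) and control 6 (triangles). Gpnmb at 983 CPM and Axl at 18.9 CPM in the knockout lie on opposite sides of their controls within the same list.

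Hypoxia and glycolysis genes and ribosomal protein genes rose as lists, and G2 and M phase genes fell. The glycolysis list had a median log2 fold change of 0.66 with the knockout highest in 18 of 26 members (camera adjusted p = 0.00157), the ribosomal list had 0.51 (0.29 over control 5 and 0.68 over control 6) with 31 of 35 highest (adjusted p = 0.000262) and the G2 and M phase list had -0.29 with 23 of 35 lowest (adjusted p = 0.000555). Each had adjusted p = 0.773 with an estimated correlation, and no member of the 3 lists passed over all genes or adjusted over the list alone. Hk2, Ldha, Tpi1 and Gpi1, all glycolytic enzymes, had 350, 997, 298 and 319 CPM against control means of 177, 540, 161 and 179. Rpsa had 153 CPM against 73.0 ± 7.84 CPM in controls (SD, n = 2), though ribosomal protein genes have many near-identical pseudogenes. Hmmr, a spindle protein, had 102 against 211 ± 24.6 CPM and Cdc25c, a mitotic phosphatase, had 253 reads against 649 and 652. The G2 and M phase median was -0.37 over control 5 and -0.11 over control 6, and with control 5 as the odd library that list was called higher (adjusted p = 0.0203). With control 6 as the odd library, the ribosomal list was called lower (adjusted p = 3.12e-09).

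The eosinophil, mast cell and granule-precursor list rose, with a median log2 fold change of 1.67 and the knockout highest in 8 of 14 members (camera adjusted p = 0.0216; adjusted p = 0.773 with an estimated correlation). No member passed over all genes, and 1 passed adjusted over the list alone, the lower Prg2. Its median was 4.09 over control 5 and 0.78 over control 6, because several members had 0 reads in control 5. Cpa3, a mast cell protease, had 23.1 CPM in the knockout library, 0 in control 5 and 13.7 in control 6, and Mpo, the granule enzyme myeloperoxidase, had 12.1, 0 and 5.85. Siglecf had 119 CPM against 21.7 and 57.9. With upper-quartile factors the adjusted p of the list was 0.0570, and with control 6 as the odd library the list was called higher with a smaller adjusted p (0.00410).

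The other 21 lists tested did not pass. Over members at a mean of 5 CPM or more, a set chosen after the data were seen, neurons and the unfolded protein response passed as lower (adjusted p = 0.0431 and 0.0107), and the latter also with genes in either table (0.0394). Among lists of other cells that a sort of embryonic brain could hold, medians were -0.57 for neurons (adjusted p = 0.289), -0.04 for neural progenitors (0.811, with a mean of 0.95), 0.70 for endothelial cells (0.764), 0.00 for erythroid cells (0.825) and 0.46 for monocytes and neutrophils (0.183). Stmn1, the most abundant neuronal gene, had 176 CPM against 203 ± 8.14 CPM in controls (SD, n = 2), and Nes, an intermediate filament of progenitors, had 97.0 against 105 ± 11.5. The oligodendrocyte and mural lists had 4 tested members each and were not tested, though with no low-count filter the mural list had 7 and was called higher (adjusted p = 0.0304). Pan-macrophage and complement genes had a median of -0.05 (adjusted p = 0.417), with C1qb at 2643 against 4142 ± 221 CPM and Lyz2 at 3131 against 2287 ± 305.

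Further medians were -0.11 for the BAF complex (adjusted p = 0.289), 0.12 for Polycomb and related histone modifiers (0.420), 0.09 for Wnt signalling (0.337), 0.09 for S phase (0.825) and 0.15 for cell cycle inhibitors and p53 targets (0.920). In the last pair of lists the test pointed lower. They were 0.14 for inflammatory cytokines (0.838), 0.04 for antigen presentation (0.838), -0.02 for phagocytosis and lysosome (0.236), 0.32 for cholesterol and lipid handling (0.344) and 0.50 for extracellular matrix and proteases (0.289). They were -0.26 for secreted growth factors (0.572, where the test pointed higher), -0.04 for dissociation stress (0.883), 0.18 for the respiratory chain (0.883, where the test pointed lower), -0.08 for the unfolded protein response (0.0592) and -0.56 for sex-linked genes (0.140, with a mean of 1.25). In the sex-linked list the knockout was lowest in 4 of 5 members, the Y-linked Uty, Ddx3y, Eif2s3y and Kdm5d. The remaining member was highest in the knockout library and had 0 reads in both controls. Uty had 46.3 CPM against 123 in control 5 and 82.3 in control 6, and Ddx3y had 182 against 367 and 241. Whether the samples differed in sex makeup was not tested, and with 1 knockout library it cannot be told apart from the genotype. Dpf2 and Smarcb1, the most abundant BAF genes, had 193 and 170 CPM against control means of 241 and 194.

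**Figure D3:**
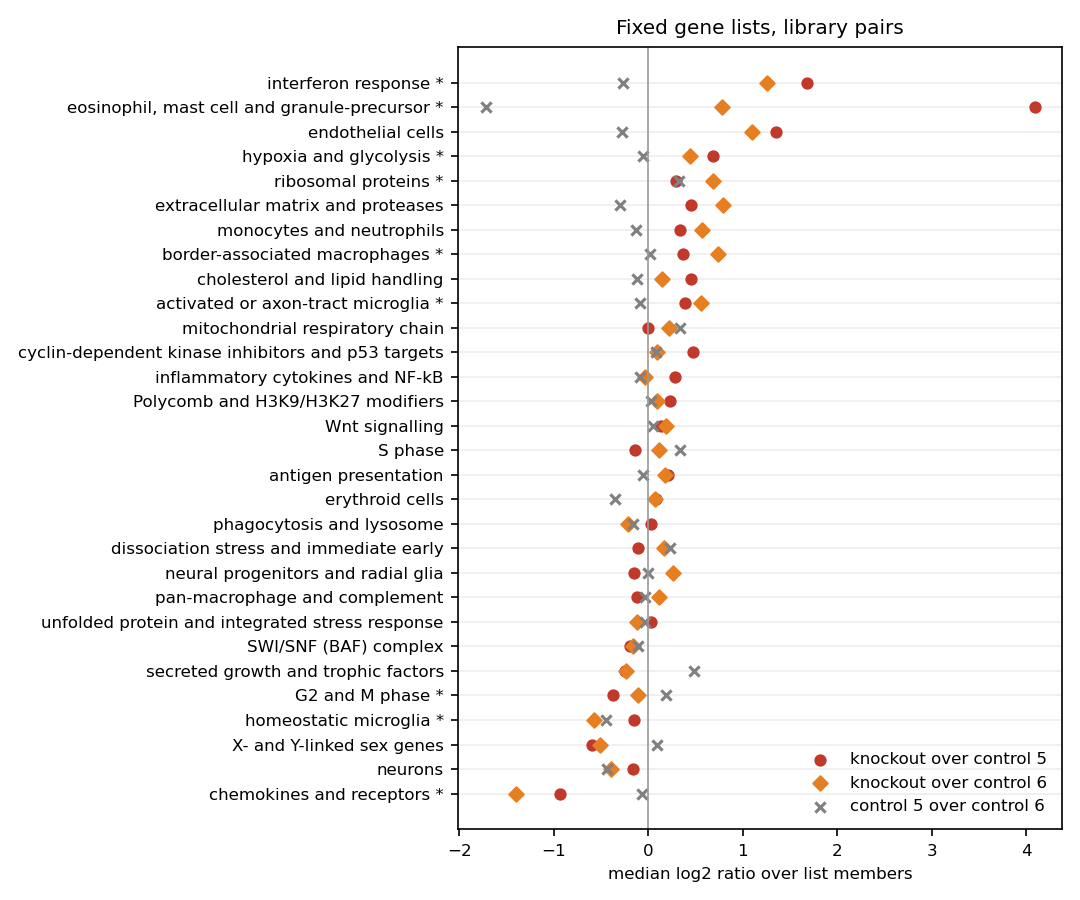
Median log2 ratio over the tested members of the 30 gene lists, for the knockout over control 5 (circles), the knockout over control 6 (diamonds) and control 5 over control 6 (crosses). Asterisks mark the 9 lists past the camera test with the preset correlation. The interferon list stood at 1.68 and 1.26 over the 2 controls, with -0.27 between the controls.

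The deposited tables compare the same knockout library with each control in turn, so their ratios share its noise. Of 15236 genes, 69.1% lay on the same side of both controls, 5785 above and 4743 below. The 95% exact binomial interval, 68.4% to 69.8%, takes the genes as independent, which they are not, so it is too narrow. Siglech had log2 ratios of -3.97 and -4.18 and Gdf3 had 3.94 and 4.55. A knockout library drawn with no change gave a mean of 62.1% (highest of 100 draws 62.9%), and 3 libraries with no difference between them would give 66.7%. The 66.7% does not allow for the genes with few knockout reads that the shared set leaves out. The covariance of the ratios was 1.155 against 0.487 in those draws, and their correlation across genes, which are not independent replicates, was 0.526 against 0.300. At 2-fold or more over both controls there were 1406 genes higher and 1054 lower, where independent lists would share 596 and 266. The unchanged draws gave means of 403.31 higher and 1344.63 lower, so the lower genes did not exceed those draws. Each draw was centred on the mean of the 2 controls, which lowers the share on the same side. Its counts were skewed, which favours values below that mean. The draws therefore cannot settle an excess in either direction. The 2 controls cannot be split, and part of any excess may come from the shared library. With control 5 as the odd library the share was 72.2%, and with control 6 it was 58.7%.

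**Figure D4:**
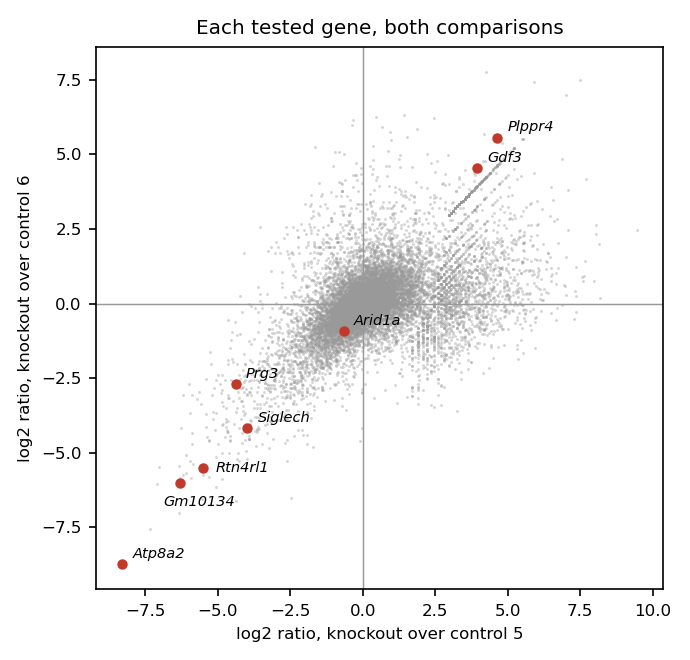
Log2 ratio of the knockout library over control 5 (horizontal) and over control 6 (vertical) for each of 15236 tested genes, with a prior count of 2. The 6 genes past the test, Arid1a and Prg3 are marked. Both axes share the knockout library, and Siglech lies at -3.97 and -4.18.

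In the authors' deposited table against control 5, 5078 of 17229 genes were marked as significant, 3743 higher and 1335 lower in the knockout. In the authors' deposited table against control 6, 3354 of 17952 were marked, 1811 higher and 1543 lower. Marked higher in both tables were 1268 genes and marked lower in both were 490. The tables share the knockout library, and the number that no change would give was not computed for these marks. Another 142 genes were marked in opposite directions. Prg3 was marked lower in both of the authors' deposited tables, with log2 fold changes of -6.32 and -4.50. Its knockout count was 0, so the size of these changes rests on the 0.5 reads put in its place. Arid1a was marked in neither, with -0.53 and -0.81. These marks compare single libraries, not the conditions.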

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

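Among the alternatives below, genes in either table, bias-adjusted quasi-likelihood, protein-coding genes, abundant list members and, for the share of genes on the same side, each control as the odd library were chosen after the data were seen. The count of 6 changed genes became 0 with DESeq2 size factors, 0 with upper-quartile factors and 0 with no low-count filter. It became 44 with 5 CPM or more in 2 libraries, 48 with protein-coding genes only, 10 with genes in either table, 14 with bias-adjusted quasi-likelihood and 21 at an FDR of 0.10. It became 158 with the likelihood ratio test, 164 with limma-voom and 222 with the DESeq2 Wald test. The 2 stricter sets test fewer genes (9628 and 12621), and the DESeq2 Wald test gave an adjusted p to 11488. What else moved the counts was not tested. All 6 genes were called by each of these that called any, except that limma-voom called 5 and left out Atp8a2 (adjusted p = 0.503). On the log2 scale, the alternative scalings shifted the knockout against the mean of the 2 controls by -0.004 and 0.004. Shifts against each control alone, which can differ, were not computed.

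The 9 gene lists called became 0 with an estimated correlation and 0 with fry, whose lowest adjusted p was 0.324. Fry asks a different question. With 1 residual degree of freedom, the test with an estimated correlation could hardly call any list. The chemokine list, with an estimated correlation of -0.048, and the homeostatic list, with 0.441, both had adjusted p = 0.773. For the chemokine list that loss therefore cannot be read as an effect of correlation between genes. Under other scalings, filters and member sets 8 to 11 lists passed, those gained being neurons (0.0431) and the unfolded protein response (0.0107, and 0.0394 with genes in either table) as lower, and with no low-count filter mural cells (0.0304) as higher. Neither Arid1a, Prg3, the genes named for the largest changes nor the 9 lists changed direction; members named within lists were not refitted. Lists that did not pass changed direction, none of them passing: with fry, neural progenitors (adjusted p = 0.882), S phase (0.921), p53 targets (0.394), dissociation stress (0.775) and respiratory chain (0.882); at 5 CPM or more in 2 libraries, endothelial (0.845), S phase (0.990), p53 targets (0.921), dissociation stress (0.775) and respiratory chain (0.869). With no low-count filter these were antigen presentation, progenitors and erythroid cells (each 0.949), with upper-quartile factors p53 targets (0.935), with genes in either table dissociation stress (0.976) and with abundant members antigen presentation and dissociation stress (each 0.966). Arid1a kept a negative log2 fold change that did not pass (-0.92 to -0.66). Without either control no residual degrees of freedom remain, so there is no count of calls. The share of genes on the same side of both controls, 69.1%, was 71.3% at 5 CPM or more in every library, 72.2% with control 5 as the odd library and 58.7% with control 6. The cause was not tested. The 1758 genes marked alike in both authors' tables became 2665 at 2-fold, a looser limit by construction. They became 1360 when the authors' adjusted p also had to be 10 times below its highest value among the marked genes of that comparison. Depth limits the genes under about 3 reads, and the simulated test rarely found 2-fold changes (0.8%). No paired analysis was possible because the groups share no replicate number.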

Other observations

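The tests on eosinophil-lineage genes and on the makeup of the sorted cells were chosen after the values had been seen. The tests of absent genes and of the number of genes and lists called under the other groupings were fixed before their results. Some members of lists that did not pass lay far from both controls, and passed when adjusted over their own list alone and not over all genes. They are named here for their small p, outside the naming rule. Serpine2, a secreted protease inhibitor, had 1015 CPM in the knockout library against 3489 and 4174, and the matrix protein fibronectin (Fn1) had 84.2 against 17.6 and 18.7. Phgdh, the entry enzyme of serine synthesis, had 28.5 CPM against 184 and 385. Among growth factors, Hgf had 1612 reads against 126 and 297. The chemokine receptor gene Cxcr2 had 7.66 CPM against 73.6 and 83.1, and the class I molecule H2-D1, one of several paralogs, had 263 against 54.4 and 71.0.

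Control 5 stood apart from the other libraries. It had 0 reads for all 9 of a set of mast cell, basophil and progenitor genes picked after seeing the data, Hdc, Cpa3, Mpo, Kit, Mcpt8, Gata1, Gata2, Itga2b and Prtn3, while the knockout library had reads for each and control 6 had reads for 7. Hdc, which makes histamine, had 355 reads in the knockout library and 316 in control 6. Cpa3 had 422 against 185, Mpo 221 against 79, Gata1 50 against 0 and Gata2 55 against 0. By CPM, Hdc and Prtn3 were lower in the knockout library than in control 6, and the others of the set were higher. Over all tested genes the log2 CPM correlation of the knockout was 0.907 with control 6 and 0.858 with control 5, against 0.893 between the controls. Among the 3752 genes at a mean of 50 CPM or more, the controls were nearest each other (0.910, against 0.863 and 0.815).

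Genes silent in the knockout library, such as Atp8a2, may reflect random loss of molecules in library preparation. At 5 CPM or more in both other libraries, 8 genes had 0 reads in the knockout (exact Poisson interval 3.5 to 15.8), 60 in control 5 (45.8 to 77.2) and 2 in control 6 (0.2 to 7.2). At 20 CPM or more there was 1 such gene in the knockout library, Atp8a2, 2 in control 5 (Hdc and Rexo1) and 0 in control 6. Random loss needed both controls to lack at least as many genes as the knockout, and 1 of them did, so for these genes it and the genotype cannot be told apart. The knockout's silent genes were not short (median exon length 5302.5 bases against 4666 for all genes at that level).

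The low Prg2 and Prg3 reads may come from fewer eosinophil-lineage cells among the sorted cells. Only Siglecf and Ccr3 of the other lineage genes were detected with at least 10 reads in total, and they went opposite ways, with a median log2 fold change of -0.04. Siglecf was higher in the knockout library (119 CPM against 21.7 and 57.9) and Ccr3 lower (0.766 against 1.56 and 3.34). With 2 detected genes on opposite sides, a smaller eosinophil share, the genotype and the lone library cannot be told apart. The sort itself was by fluorescence, and its markers were not given in the sources used here.

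The lower homeostatic genes and higher border-macrophage genes could come from more border-associated macrophages. The core markers of those cells did not rise as a set. Their median log2 ratio was -0.01 over control 5 and 0.17 over control 6, and the abundant Mrc1, Stab1 and F13a1 reached at most 0.17, while Dab2 had a log2 fold change of 1.70. These markers were picked after the values were seen and leave out Dab2, Ednrb and Ms4a6b, which rose, so they cannot exclude this cause. Of the 5 core markers at a mean of 5 CPM or more, the only ones used, Cbr2 was at 1 or more over both controls. Fewer microglia with more neurons stays open. Over all neuron members the medians were -0.16 over control 5 (error 0.26) and -0.40 over control 6 (error 0.21), both within 2 errors of 0. Over members at a mean of 5 CPM or more, taken after that, they were -0.46 (error 0.20) and -0.42 (error 0.17). As a median log2 fold change, the neuron list was at -0.57 (error 0.20, 12 members above 0 and 21 below). Pan-macrophage and complement genes, which fewer microglia would also lower, had a median of -0.05 (error 0.21, 11 above 0 and 12 below). The homeostatic list had -0.50 (error 0.17, 11 above 0 and 26 below). With 1 knockout library these medians do not settle the question. More vascular or progenitor cells stays open too, with an endothelial median of 0.70 (error 1.16, 10 members above 0 and 6 below) and a progenitor median of -0.04 (error 0.26), as do a changed state of the microglia, which the design names, and a difference between single samples.

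Of the 3 ways to set 1 library against the other 2, the real one called 6 genes and the highest other 0, and it called 9 lists and the highest other 7. At an unadjusted p under 0.05 it gave 914 genes, control 5 as the odd library 1971 and control 6 117. For the genes and for the lists called, 1 of 3 groupings reached the real count, while at the unadjusted p 2 of 3 did. With 3 groupings no share under 0.05 can be had.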
